A study of Homo sapiens with 4 samples.

How the data were processed

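Total RNA from T84 cells was labelled and hybridised to Affymetrix U133 Plus 2.0 arrays, per the labels' protocols. Cells were seeded at 500000 per well on filters of 24 mm diameter with 0.4 µm pores, were transfected with 15 pmol of oligonucleotides and received fresh medium every other day, per the labels; whether the amount was the total of a mix or that of each oligonucleotide is not given in the sources used here. The deposited table holds an intensity for each of 54675 probe sets on each of 4 arrays, on a linear scale with no negative values. The authors computed these intensities with MAS5, per the submitters' processing notes; its version and scaling target are not given in the sources used here. The trimmed means of the deposited columns differed (147, 150, 76.6 and 74.3 for the 2-miRNA, 4-miRNA, day 5 control and day 7 control arrays), so the deposited values were taken as not scaled to a common level, and the columns' medians were 25.7, 24.5, 15.2 and 14.7. The highest value was between 17832 and 18749 on every array. No scan date or batch was given, and the brighter pair of arrays is the miRNA pair, so brightness and miRNA treatment coincide.

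Each array was multiplied by a factor (3.39, 3.33, 6.53 and 6.73) that set its mean, after leaving out the lowest and highest 2% of probe sets, to 500, and 32 was added before taking log2. Folds are therefore on the scale of signal plus 32 and understate differences of dim genes. Gene names came from the platform annotation supplied with the table: 41097 probe sets had 1 gene symbol, 1801 had several and were left out, and 11777 were unnamed here. Of the named ones, 41043 matched the NCBI gene table of GRCh38.p14 by gene ID, which was used for names alone; no coordinates are given because no build applies to the table. A probe set was kept when its mean log2 over the arrays was at or above the median of all probe sets or when it reached the 75th percentile of any array. The probe set with the highest mean stood for its gene, which left 12264 genes, 5896 of them with 2 or more expressed probe sets.

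The comparisons, the 35 gene lists with 676 entries, the rule for naming genes and the alternatives were fixed before the data were examined. The comparisons were each miRNA array minus the day 5 control, the 4-miRNA array minus the 2-miRNA array, and the day 7 control minus the day 5 control. With 1 array per group no test across samples exists, and genes were counted at an absolute log2 difference of 1 or more. A list with at least 5 expressed members was described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins; it was said to be high or low when it was in the highest or lowest 2.5% of them. Over the 4 comparisons 128 such medians were computed, of which 6.4 are outside by chance if genes vary independently, and 33 were. Genes regulated together can move together between any pair of cultures, and comparisons with the day 5 control share that array. An excess over the chance count therefore does not by itself speak for an effect of time or miRNAs. Fibroblast, leukocyte and endothelium markers, listed as checks for other cells, had 3, 3 and 2 expressed members and were too few for a percentile.

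Genes were named by this rule, per comparison. The first part took the 12 largest positive and 12 largest negative differences of at least 1 among genes at or above the median of both arrays, leaving out genes whose other expressed probe sets differed in sign. Genes with 1 expressed probe set, 6368 of the 12264, passed this limit on sign without a check. The second took the 3 largest in each direction among genes under the median of 1 array and at or above the 75th percentile of the other; their fold, like that of any other named gene under the median of 1 array, is given as a lower bound, the brighter signal over the median of the dimmer array. The third took up to 4 members of each list past the threshold, largest first, and the last took ITGB1, CDH1, TJP1, OCLN, GAPDH, ACTB and the reported targets of the miRNAs always. The text names the larger differences of each part.

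Error of probe sets was taken from the array itself, and variation between cultures could not be measured. For 2268 genes with 2 probe sets at a mean log2 of 9 or more, the difference between the probe sets' log2 differences gave the SD specific to a probe set, and the covariance of the pair the SD shared by the gene. Correlations of differences that share a control were set beside 100 simulations of unchanged arrays with independent noise of the size between the controls. In 100 further simulations, chosen after seeing the data, each array had the noise of its kind and both miRNA arrays shared a probe-set-specific difference that made up the SD between the kinds. The bacterial control probe sets, 9 in number, were 1.75-fold, 1.47-fold and 1.14-fold the day 5 control on the 2-miRNA, 4-miRNA and day 7 arrays as deposited, and 0.909-fold, 0.752-fold and 1.17-fold after scaling. The ratio of 3' to 5' probe sets was 2.28, 1.97, 2.11 and 2.33 for ACTB and 0.962, 0.951, 1.02 and 0.978 for GAPDH on the 2-miRNA, 4-miRNA, day 5 control and day 7 control arrays; for GAPDH both signals were near the top of the range, where a ratio says little.

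The procedure was tested on simulated data for the 2-miRNA array minus the day 5 control, over 12284 genes, with the noise of the control pair. All 100 genes given a 4-fold difference and 96.0% of 100 genes given a 2.83-fold difference were recovered past 2-fold with the right sign. Of 12084 unchanged genes, 0.0166% passed it by chance. That share is too low for the data, because dim genes were noisier: the SD between the controls was 0.68 in the dimmest of 5 level bins. The separate simulation set beside the counts gave 176 higher and 176 lower genes between the controls. With the larger noise seen between that miRNA array and the day 5 control, 95.0% and 82.0% were recovered, and 10.1% of 12111 unchanged genes passed 2-fold by chance. Both noise levels were measured on genes at a mean log2 of 9 or more. The shares recovered, at either noise level, therefore apply to bright genes and do not cover the dimmer genes among those reported. For simulated control arrays, 4.00% of 200 unchanged lists of 20 genes were outside the central 95%. These genes were drawn at random with independent noise, so this share does not cover lists whose genes move together. The alternatives were median centring, quantile normalization, pseudocounts of 8 and 100, no filter, a filter at the 70th percentile, the median over expressed probe sets, genes with several probe sets of the same sign alone, and the day 7 control as the control. Centring each array by a running median over signal level in 200 bins was added after seeing that the arrays differed in brightness. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.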

Results

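T84 cells, a human colorectal carcinoma line that forms polarised epithelial layers, were grown on permeable filters and transfected with oligonucleotides for microRNAs (miRNAs), short RNAs that lower the level or the translation of messenger RNAs with matching sites. The study concerned miRNAs in the formation of epithelial polarity, the separation of an apical surface from a basolateral surface that adheres to its support through β1-integrin. Messenger RNA was measured on Affymetrix U133 Plus 2.0 arrays, with 1 array in each of 4 groups. The 2-miRNA array held cells given miR-338-3p and miR-451 and collected on day 5, and the 4-miRNA array cells given those 2 together with miR-33a and miR-210 and collected on the same day. The control arrays held cells given a negative-control short RNA and collected on day 5 or day 7. As deposited, the trimmed mean signal was 147 on the 2-miRNA array and 150 on the 4-miRNA array, against 76.6 on the day 5 control and 74.3 on the day 7 control. After each array was scaled to a trimmed mean of 500, 12264 expressed genes were compared. No group had a replicate, so no test across samples was possible, no p-value is given and the number of arrays limits the precision. Differences are log2 values of scaled signal plus 32, and a gene at least 2-fold apart is 1 with an absolute log2 difference of 1 or more. The disagreement between probe sets of the same gene is given as a measure of probe set error. It leaves out variation between cultures, transfections and RNA preparations, which was not measured. A count above a simulated count therefore does not by itself speak for time or treatment.

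The control arrays of day 7 and day 5 address what 2 further days on the filter went with. Genes of absorptive enterocytes, the mature cells of the intestinal surface, were higher on day 7, led by AQP8, a water channel (log2 difference 3.97, scaled signal 4950 against 286), and SLC26A3, the apical chloride-bicarbonate exchanger (3.76, 3417 against 223). All 21 expressed members of that list lay above 0, with a median of 0.51, CEACAM7 was higher by 2.51, and ANPEP, a brush border peptidase under the median of the day 5 array, was at least 2.16-fold higher. Of 20 goblet and secretory cell genes, 13 were above 0 with a median of 0.35, among them the secreted trefoil peptides TFF3 (2.18) and TFF1 (1.48) and the mucus lectin ZG16 (1.58). Targets of the hypoxia-inducible factor HIF were higher as well: 11 of 19 were at least 2-fold higher and the list median was 1.17, with EGLN3, a prolyl hydroxylase that marks HIF for destruction, at 2.21, NDRG1 at 1.71, ANKRD37 at 1.58 and DDIT4 at 1.48. Genes of DNA replication were lower, 22 of 26 below 0 with a median of −0.35, and so were genes of mitosis, 21 of 28 below 0 with a median of −0.20.

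Over all genes, 411 were at least 2-fold higher on day 7 and 296 at least 2-fold lower. Simulated arrays with the disagreement between probe sets alone, without variation between cultures, gave 176 and 176. Among genes at or above the median of both arrays whose probe sets had the same sign, those with the largest positive differences besides the genes above were RNF186 (2.83), MRAP2 (2.60), SMIM24 (2.41), MUC20, a membrane mucin (2.22), APOBEC3C (2.16), SLC11A2, an iron transporter (1.96), and SLC25A24 (1.95). Within the same limit the largest negative differences were GNB1L (3.99-fold lower), UBE2NL (−1.60), TIMM29 (−1.46), PGAM5 (−1.45), RAD54L2 and SNX22 (both −1.37) and DDX51 (−1.36). CLDN2, a tight junction protein that forms a cation pore, was lower on day 7 on its single expressed probe set (−1.34, 1239 against 3179). LGI4 and CASTOR2 were under the array median on 1 side: LGI4 was at least 4.15-fold higher and CASTOR2 at least 3.67-fold lower. VIM, the mesenchymal intermediate filament protein, was at least 2.16-fold higher, also from under that median, while the other 6 expressed genes of the epithelial-mesenchymal list stayed within 2-fold.

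Against 10000 random lists of the same size and expression, 11 of 32 lists were outside the central 95% in this comparison. By chance 1.6 are outside if genes vary independently. The absorptive, goblet, hypoxia and glycolysis lists were at or above the 99.9th percentile, and glycolysis had 14 of 15 genes above 0 with a median of 0.45, ALDOC (1.82) the only member at least 2-fold higher. The adherens junction and desmosome list (median 0.25), the interferon response (0.24), the immediate early genes (0.26) and the reported miR-33a targets (0.23, 0.14 with the 70th percentile filter) were also high. With the median over probe sets the adherens junction and immediate early medians were 0.07 and 0.11. Heat shock genes were low, with 0 of 9 above 0 and a median of −0.24. Tight junction genes, with 16 of 19 above 0 and a median of 0.15, and integrin and laminin genes, with a median of 0.16, were within the central 95%, as were brush border genes (0.22, percentile 96.8, but 98.1 and outside with quantile normalization). With quantile normalization the adherens junction list and the miR-33a list were no longer outside (percentiles 97.2 and 96.3). With 2268 genes that had a pair of well-measured probe sets, the SD between probe sets of the same gene was 0.27 and the SD shared by both was 0.26.

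**Figure D1:**
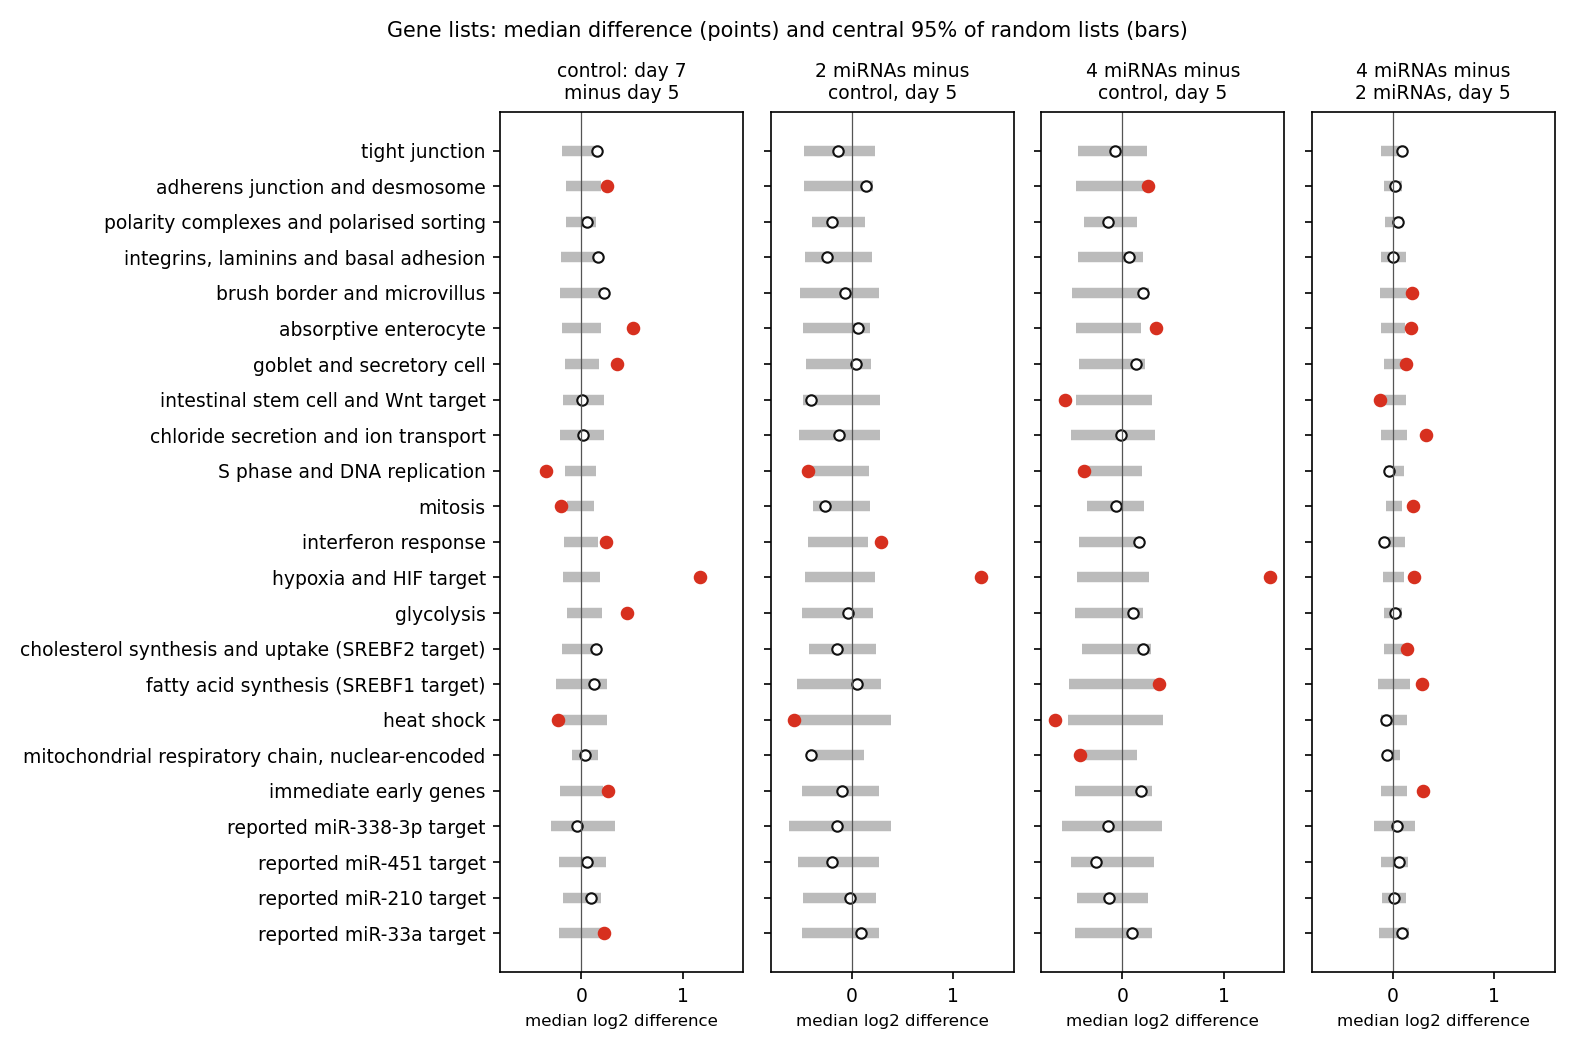
Median log2 difference of selected gene lists (x axis, points) in the 4 comparisons (panels). Grey bars are the central 95% of 10000 random lists of matched size and expression. Filled red points are outside the bar and open points inside. Shown are the lists outside the bar in any comparison, and the tight junction, polarity, integrin and reported-target lists. Other lists that were inside the bar in every comparison are left out. The hypoxia list stands at 1.17, 1.27 and 1.46 in the comparisons with the day 5 control, and the absorptive enterocyte list at 0.51 in the day 7 control.

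The 2-miRNA array was compared with the day 5 control to see what miR-338-3p and miR-451 together went with. FOLR1, the folate receptor of epithelial surfaces, had the largest positive difference among genes measured on both sides whose probe sets had the same sign (3.56, 4846 against 383), followed by NCKAP1, a subunit of the actin-regulating WAVE complex (3.49), SDHAF3 (3.37) and ACSL4 (3.17). PARD6B, a scaffold of the apical polarity complex, was higher by 2.81 on its single probe set, and ITGB8, an integrin subunit, was at least 8.17-fold higher, from under the median of the control array to 1041. CLDN2 was lower (−2.05, 745 against 3179), as were TRMT1 (−2.35), NAGPA (−2.26), RANGAP1 (−2.17) and NUP93, a nuclear pore protein (−1.99). HIF targets were higher, with 12 of 19 at least 2-fold higher and a median of 1.27, led by PDK1, the kinase that restrains pyruvate oxidation (2.44), EGLN3 (2.24), PFKFB3 (1.72) and DDIT4 (1.68). Against the day 7 control their median was 0.03.

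Among the fixed lists, the interferon response was also high, with 20 of 27 genes above 0 and a median of 0.29. Its largest members were the RNA sensors IFIH1 (2.24) and RIGI (1.21) with IFIT2 (1.38) and IRF9 (1.07). Against the day 7 control the list's median was −0.16, at percentile 56.2 and so inside the random range. Absorptive enterocyte genes, with a median of 0.06 at percentile 91.7, were inside the range, but at 0.25 and percentile 98.3 with quantile normalization and outside it. DNA replication genes were low, with 21 of 26 below 0, a median of −0.43 (−0.03 against the day 7 control) and CHAF1A at −1.29, MCM7 and E2F2 both at −1.08, and CDT1 on the other side at 1.24. Heat shock genes had a median of −0.58 with 7 of 9 below 0, CHORDC1 at 1.78 being the exception past 2-fold, but with quantile normalization this list moved to −0.23 at percentile 26.1. Of 33 polarity and sorting genes, PARD6B, PATJ (1.96) and STX3 (−1.09) were at least 2-fold apart and the median was −0.20, within the random range. Of 22 integrin, laminin and basal adhesion genes, 5 were at least 2-fold higher, ITGB8, ITGA2 (2.35), ITGA6 (1.77) and ITGAV (1.63) leading. LAMA5 (−1.31) was at least 2-fold lower, and the list median was −0.24, also within the random range. Adherens junction genes reached 1.30 for CTNNB1, the β-catenin gene, 1.19 for PKP2 and 1.10 for DSC2, and their median of 0.14 was within the range. Of 20 goblet and secretory genes, 5 were at least 2-fold lower, CLCA1 (−1.58) and DEFA5 (−1.63) among them, and 1 at least 2-fold higher, LYZ (1.86). AGO4 (1.74), DICER1 (1.39) and XPO5 (−1.20) were the RNA silencing genes past 2-fold.

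In total, 995 genes were at least 2-fold higher and 781 at least 2-fold lower than in the day 5 control, from a median gene at −0.16. Simulated arrays with the disagreement between probe sets alone gave 663 and 664, so much of each count may come from it. With each array centred by a running median over signal level, the split was 1149 higher and 587 lower. Further genes with large positive differences were MED23 (3.04), BLZF1 (3.01), PPIL4 (2.99), RAD21, a cohesin subunit (2.83), ARRDC3 and RB1, the retinoblastoma protein gene (both 2.82), and CRIM1 (2.75). Further negative ones were RGMB (−1.89), AAAS and CIZ1 (both −1.85), SMOC2 and UBE2O (both −1.82), and MAD2L2 and TMEM39B (both −1.75). Probe sets of the same gene disagreed more here than between the controls: the SD between them was 0.61 and the shared SD 0.40, and for RAD21 the pair of probe sets gave 0.07 and 2.83. Of 791 genes past 2-fold with several expressed probe sets, 58.7% had all of them on the same side of 0 and 11.9% had all of them past 2-fold.

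Adding miR-210 and miR-33a to the mix gave an array that also differed from the day 5 control by FOLR1 (3.76, 5584 against 383), SDHAF3 (3.11), RB1 (2.98) and PARD6B (2.97). CLDN2 (−2.41), SMOC2, a secreted protein of the intestinal stem cell programme (−2.27), and KRT23 (−2.13) were the lowest among genes measured on both sides with probe sets of the same sign. For CLDN2, with a single expressed probe set, that limit on sign checks nothing. SP5, a direct target of Wnt signalling, was at least 4.76-fold lower. HIF targets were again higher, 16 of 19 by at least 2-fold with a median of 1.46, among them EGLN3 (2.74), PDK1 (2.38) and DDIT4 (1.90), and against the day 7 control their median was 0.24 at percentile 99.2. Intestinal stem cell and Wnt target genes were low, 10 of 14 below 0 with a median of −0.56 (−0.02 with the 70th percentile filter and −0.24 with no filter) and SP5, SMOC2 and EPHB3 (−1.10) past 2-fold. Absorptive enterocyte genes were high against the day 5 control (median 0.34, 0.00 with no filter on low signal and 0.03 with the median over probe sets). SLC26A3 stood at 2.46 and AQP8 at 1.93, and ANPEP was at least 2.70-fold higher, but 9 of 21 lay below 0. Against the day 7 control the same list had a median of −0.40, just inside the random range, and in the 2-miRNA array its median against that control was −0.68 at percentile 0.010. Of 64 list medians of the 2 miRNA arrays against the day 7 control, 9 were outside the random range, where 3.2 are by chance for independent genes. Besides those given, with 2 miRNAs these were goblet cell (−0.53), glycolysis (−0.53) and metallothionein genes (−0.48), and with 4 miRNAs goblet cell (−0.40), stem cell and Wnt target (−0.50), the respiratory chain (−0.47) and enteroendocrine genes (0.50).

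Other lists outside the random range on the 4-miRNA array were adherens junction and desmosome (median 0.25, 0.50 after running-median centring, with DSC2 at 1.19 and PKP2 at 1.17), fatty acid synthesis (0.36, 0.20 with the median over probe sets, with FADS2 at −1.09 the member past 2-fold), DNA replication (−0.38, MCM5 at −1.18 and MCM7 at −1.11), heat shock (−0.66) and the nuclear-encoded respiratory chain (−0.42, no member past 2-fold). With quantile normalization the DNA replication, heat shock and respiratory chain lists moved inside it (percentiles 3.44, 8.80 and 4.07), the last 2 to medians of −0.35 and −0.26. With running-median centring the DNA replication median was −0.20. Against the day 7 control the adherens junction, DNA replication and fatty acid medians changed sign, but inside the random range (percentiles 57.6, 85.2 and 79.0). The interferon list, with a median of 0.16, was at percentile 97.4 and just inside, but at 99.3 and outside with quantile normalization. Counts were 985 genes higher and 822 lower by at least 2-fold (661 and 672 in that simulation) from a median gene at −0.15, or 1151 and 578 after running-median centring. Further genes on the higher side were CRIM1 and ACSL4 (both 2.90), SCIN, an actin-severing protein (2.88), RBM48 (2.87), ARRDC3 (2.83), PPIL4 (2.69) and CALB1 (2.65), and RP2 was at least 13.5-fold higher. On the lower side were RGMB (−2.12), NUP93 (−2.10), NOP2 (−1.97), KAT2A (−1.91), HPDL (−1.90), TMEM138 (−1.89), C1orf216 (−1.86), EEF2KMT (−1.85) and CTPS1 (−1.84). Of 774 genes past 2-fold with several expressed probe sets, 54.1% had them all on the same side of 0, and HK2 (1.88) was lower, not higher, by the median over its probe sets.

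**Figure D2:**
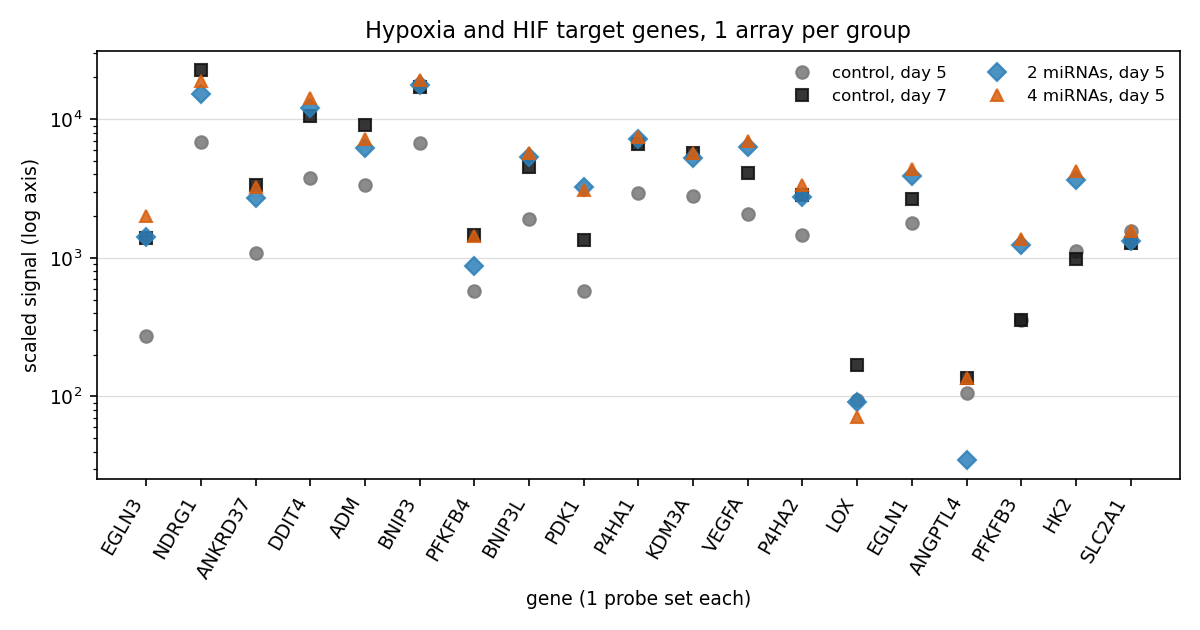
Scaled signal (y axis, log scale) of the 19 expressed hypoxia and HIF target genes (x axis) on the 4 arrays, 1 point per array. EGLN3 stands at 274 on the day 5 control and at 1381 or above on the other arrays, while HK2 and PFKFB3 are higher on the miRNA arrays alone and SLC2A1 is within 2-fold throughout.

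The 4-miRNA and 2-miRNA arrays were compared to see what went with miR-210 and miR-33a. Whether the 15 pmol of oligonucleotides was the total of a mix is not given. If it was, the 4-miRNA cells also received less of the miRNAs held by both mixes. The comparison cannot separate such a lower dose from the added miRNAs. MEP1A, a brush border metalloprotease, was higher with 4 miRNAs (1.65, 3556 against 1113), as were SLC26A11 (1.55), H1-4, a linker histone (1.50), NHERF1, a scaffold of the apical membrane (1.23), SLC44A4 (1.21) and TFF1 (1.15). IGFBP7, a secreted binding protein of insulin-like growth factors, was lower (−1.59, 208 against 689). EFNA3, an ephrin gene reported as a target of miR-210, was lower as well (−1.50, 119 against 396). It was second among genes at or above the median of both arrays with probe sets of the same sign, but at rank 36 from the lowest over all genes. Genes of mitosis were higher, 23 of 28 above 0 with a median of 0.20, as were immediate early genes, 14 of 15 above 0 with a median of 0.30. Lists of the differentiated epithelium were higher too: chloride secretion (10 of 13 above 0, median 0.33, 0.135 with the median over probe sets), brush border (11 of 15, 0.19), absorptive enterocyte (14 of 21, 0.18, with ANPEP past 2-fold) and goblet cell (15 of 20, 0.13, 0.20 with the 70th percentile filter).

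Only 128 genes were at least 2-fold higher and 163 at least 2-fold lower in this pair (40.1 and 40.8 in the simulation), with a median gene at 0.00. Further lists above the random range were hypoxia (median 0.21, 0.14 with the median over probe sets), fatty acid synthesis (0.29) and cholesterol synthesis (0.14, MVD past 2-fold), and stem cell and Wnt targets were below it (−0.13), SP5 at least 2.49-fold lower. The stem cell list lay inside the range with quantile normalization, at percentile 5.57, and its median changed sign to 0.10 under the 70th percentile filter and was −0.06 with no filter. Of the interferon list, IFIT1 (−1.09) and OASL were at least 2-fold lower. Further single genes were TMUB1 (1.21), SGTA (1.18), CYP4F2 (1.17), KIF12 and CETN1 (both 1.16) and LRRC75B (1.14) on the higher side, and DYNC1I1 (−1.40), RAB3IL1 (−1.32), TOP6BL (−1.27) and PEX39 (−1.25) on the lower. GNAO1 was at least 3.97-fold lower. The SD between probe sets of the same gene was 0.18 and the shared SD 0.14, the smallest of the 6 pairs of arrays.

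Reported targets of the transfected miRNAs were examined as lists fixed in advance. In the 2-miRNA array against the day 5 control, 6 of 9 reported miR-338-3p targets and 9 of 13 reported miR-451 targets were below 0, with medians of −0.14 and −0.20 at percentiles 57.0 and 46.4, so neither list stood apart. MACC1, a reported miR-338-3p target, was higher by 1.86 and IL6R, a reported miR-451 target, by 1.18, while MYC was lower (−1.14), NRP1 stood at −0.78 and MIF, CAB39 and RAB14 at 0.22, −0.23 and −0.20. With 4 miRNAs the medians were −0.14 and −0.26. A lower dose of the miRNAs held by both mixes was possible on that array, as given above. Between the 4-miRNA and 2-miRNA arrays, 8 of 17 reported miR-210 targets were below 0 and the median was 0.01 at percentile 52.9; besides EFNA3, E2F3 stood at −0.31, ISCU at −0.27 and SDHD at −0.24. The 17 reported miR-33a targets had a median of 0.09 at percentile 87.4, with ABCA1 and ABCG1, the cholesterol exporters, at 0.07 and 0.72 and SLC25A25 at 1.05. BCL2, dim with 4 miRNAs, was at least 1.19-fold lower on the probe set used, but another probe set, taken under quantile normalization, put it higher.

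Genes tied to adhesion and junctions were followed in every comparison. ITGB1, which encodes β1-integrin, was within 2-fold throughout: its log2 difference was 0.39 with 2 miRNAs and 0.37 with 4 miRNAs against the day 5 control, −0.02 between the mixes (0.00 with median centring) and 0.26 between the controls. CDH1, the E-cadherin gene, stood at 0.14, 0.25, 0.11 and 0.29 in the same order, and OCLN, the occludin gene, at 0.13, 0.24, 0.11 and 0.09. TJP1, the ZO-1 gene, stood at 0.52, 0.55, 0.03 and 0.15, the third value changing sign with quantile or running-median scaling. GAPDH and ACTB are given no difference: as deposited they stood at 67.7% or more and 54.9% or more of the highest signal of each array, where a difference mainly returns the scale factors. The brightest 2% of probe sets, 1094 in number, had a median difference of −0.29 with 2 miRNAs and −0.28 with 4 miRNAs against the day 5 control, and −0.06 and −0.04 with quantile normalization.

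The differences of the miRNA arrays from the day 5 control were compared with each other and with the time difference, across genes, which are not independent replicates. The 2-miRNA and 4-miRNA differences correlated at r = 0.87, where unchanged arrays sharing that control gave 0.50 in a simulation with independent noise. With the disagreement between probe sets that sets the kinds of array apart also simulated, it gave 0.90, so the correlation does not speak for effects of the mixes. The covariance was 0.461 against 0.352 in the latter simulation. They had 803 genes higher in both and 383 lower in both, where independent lists give 79.9 and 52.3, independent noise on a shared control gave 44.2 and 45.0 and the latter simulation 446 and 447. With no shared array, the 2-miRNA array minus the day 5 control and the 4-miRNA array minus the day 7 control correlated at 0.60, below the 0.70 of that simulation. The day 7 minus day 5 difference correlated with the 2-miRNA and 4-miRNA differences at 0.51 and 0.54, where the shared control gave 0.50 with independent noise and 0.32 in the latter simulation, and its covariance with them was 0.191 and 0.202 against 0.0807 and 0.0804. All 3 other arrays were at least 2-fold above the day 5 control for 186 genes, 8 of them HIF targets, and at least 2-fold below it for 48 genes, CLDN2 among them, where independent noise gave 19.3 and 19.2 and the latter simulation 33.4 and 33.2. Of these genes, 82 and 27 were at or above the median of all 4 arrays.

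**Figure D3:**
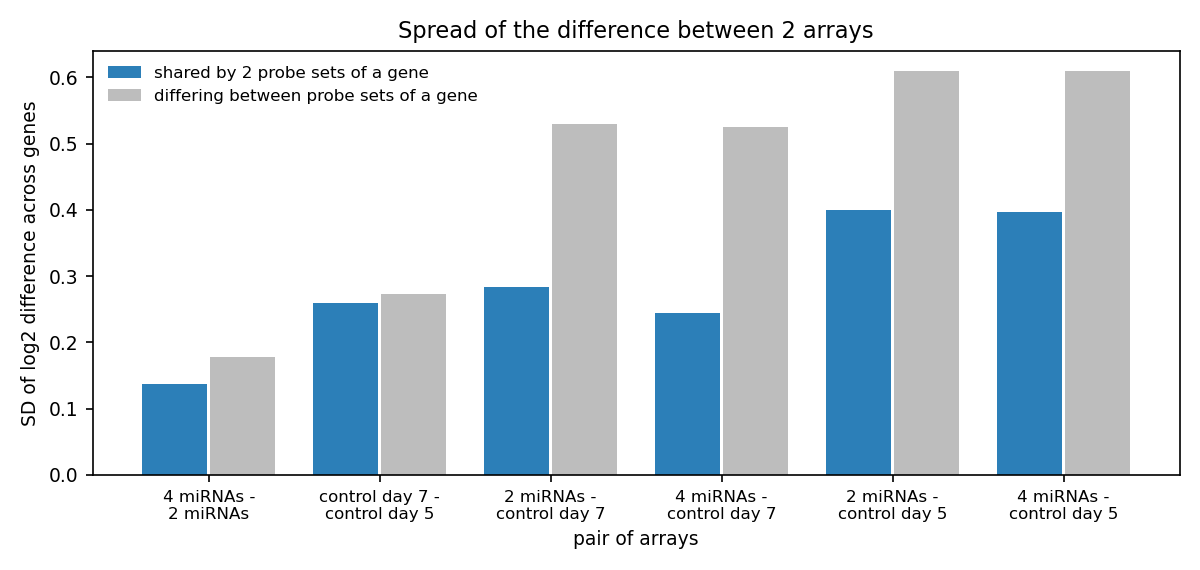
SD across 2268 genes of the log2 difference between 2 arrays (y axis), split into the part shared by a pair of probe sets of the same gene (blue bars) and the part differing between them (grey bars), for the 6 pairs of arrays (x axis). The grey bars are 0.18 and 0.27 within the miRNA and the control arrays and 0.53 to 0.61 between them.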

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

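The explanations in this part, and what each predicts, were written after the values had been seen. Among the array's control probe sets, the 5' probe set of 28S ribosomal RNA was brighter on the miRNA arrays (4653 and 4036 against 1448 and 1548). Its signal was 2.61-fold higher on the lower of the miRNA arrays than on the higher of the control arrays. For the other 5 ribosomal RNA probe sets the same ratio was 0.477 to 1.41, under 2-fold for each.

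Many more genes were 2-fold apart between miRNA and control arrays than within either kind. A shift by brightness or saturation that all probe sets of like signal level share is argued against as the only cause by running-median centring. After it 1736 genes were still 2-fold apart between the 2-miRNA array and the day 5 control, beside 706 between the controls. The centring does not remove effects of brightness or saturation that differ between probe sets of like level, so these stay open. Probe sets of the same gene disagreed at least 1.92 times as much between the kinds of array as within either kind, so most of the difference is consistent with something specific to each probe set, such as labelling or RNA fragment length, that separated the arrays. Effects of the miRNAs cannot be told apart from this because treatment and kind of array coincide. The shared SD against the day 7 control was 0.284 for the 2-miRNA and 0.245 for the 4-miRNA array, on either side of the 0.259 between the controls. Against the day 5 control it was 0.399 and 0.397, above that value for both arrays.

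HIF target genes were higher on 3 arrays than on the day 5 control. A cause in the added miR-210, a miRNA known to be induced by HIF, is argued against for the part present without it. The mix lacking miR-210 had a median of 1.27. The cells' own miR-210 was not measured, so a part played by it is not excluded. MIR210HG, its host transcript, stood at 1.06, 1.15 and 1.67 on the 2-miRNA, 4-miRNA and day 7 arrays against the day 5 control. For the rise on the day 7 array, a difference between the kinds of array is argued against by the pair of controls, of 1 kind, with a median of 1.17. For the miRNA arrays that pair cannot decide, since kind of array and treatment coincide there. It stays open whether the culture behind the day 5 control array was itself the exception, for instance in oxygen at collection. The 2-miRNA array and the day 7 control differed by a median of 0.0312, which an exceptional day 5 control and an earlier response to miRNAs both predict. The 2 cannot be told apart with 1 control of that day. The 4-miRNA array stood at 0.238 (percentile 99.2) against the day 7 control, above the random range. That value does not decide the question, since it crosses the kinds of array and is among 9 of 64 such medians outside the range.

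EFNA3, the reported miR-210 target, was lower with 4 miRNAs than with 2. Of 613 genes of like level, 3 were as low or lower, EFNA3 itself among them. Over 17 reported targets this makes 8.32% by chance, so a chance value of its single probe set is not excluded. An effect of miR-210 may be behind it, but the reported targets as a list had a median at percentile 52.9 with members on both sides of 0, which decides nothing for a single gene. A lower dose of the miRNAs held by both mixes is a further possibility, if the 15 pmol was the total of a mix. It was not tested. These explanations stay open without a replicate.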

How the results depend on the processing

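The running-median centring was chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because each group has 1 array, and the planned analysis of miRNA seed sites was not run, for lack of 3' UTR sequences here. Counts of genes 2-fold apart moved by no more than 1.5 times under median centring, quantile normalization, running-median centring and the median over probe sets, in all 4 comparisons. In the order 2-miRNA and 4-miRNA against the day 5 control, 4-miRNA against 2-miRNA and day 7 against day 5, counts of higher and lower genes were as follows where they moved further. With no filter, which lets in dim genes, they were 1611 and 1983, 1608 and 1977, 701 and 705, and 1485 and 1331. With genes that had several probe sets of the same sign alone, a smaller set by construction, they were 298 and 166, 265 and 154, 12 and 22, and 78 and 27. The 70th percentile filter, which tests fewer genes, left 391 and 408 lower genes against the day 5 control, 15 higher and 23 lower between the mixes, and 148 higher and 43 lower between the controls. A pseudocount of 100, which shrinks differences of dim genes, left 408 and 453 lower genes against the day 5 control, 29 higher and 40 lower between the mixes, and 206 higher and 113 lower between the controls, and a pseudocount of 8 gave 198 higher and 252 lower between the mixes. With the day 7 control as the control, 494 and 509 genes were lower for the 2-miRNA and 4-miRNA arrays.

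The HIF target median kept its sign in every comparison and alternative. With the median over probe sets it was 1.01 and 1.20 for the 2-miRNA and 4-miRNA arrays against the day 5 control, 0.14 between the mixes and 1.02 between the controls, and against the day 7 control it was 0.0312 and 0.238 for the mixes; the cause was not tested. Against the day 7 control other list medians changed sign: for the 4-miRNA array −0.14 for adherens junction, −0.40 for absorptive enterocyte, 0.00599 for DNA replication and −0.00862 for fatty acid synthesis, and for the 2-miRNA array −0.16 for the interferon response. The median gene itself stood at −0.15 for the 4-miRNA array and −0.16 for the 2-miRNA array against that control. In the order given, these medians were at percentiles 57.6, 2.505, 85.2, 79.0 and 56.2, all inside the random range. A changed sign here therefore does not mean an opposite difference. The absorptive median of the 4-miRNA array was −0.0034 with no filter, and the stem cell and Wnt median between the mixes was 0.10 with the 70th percentile filter. Of 276 alternative values of 33 list medians, 238 moved by less than the SD of random lists, 31 moved further with the same sign and 7 changed sign. Of 3783 alternative values of 485 gene differences, 3651 moved by less than the disagreement between probe sets. That share says little, since a change of filter largely leaves a gene's probe set as it was and median centring shifts all genes alike. With the median over probe sets, 76 of the 485 moved further and 4 changed sign. Of all values past 2-fold, 5 changed sign. With the median over probe sets EZR stood at −0.13 for the 2-miRNA array and −0.15 for the 4-miRNA array. HK2 stood at −1.18 for the 4-miRNA array and FGD2 at 0.18 between the controls, since their probe sets disagree. BCL2 stood at 1.11 between the mixes with quantile normalization, through another probe set. Dim genes are the limit of depth: in the dimmest of 5 level bins the SD between probe sets was 0.75 for the 2-miRNA array against the day 5 control, 0.48 between the mixes and 0.68 between the controls.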

Other observations

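Single members of 3 further lists were past 2-fold against the day 5 control, although each of the lists was within the random range there. Of 14 metallothionein and oxidative stress genes, with a median of −0.24 at percentile 29.1 with 4 miRNAs, MT1E and MT2A stood at −1.30, MT1G at −1.13 and MT1X at −1.12. In the unfolded protein response list of 18 genes, at percentile 53.6, CRELD2 (−1.50) and SDF2L1 (−1.10) were lower on that array and DNAJC3 (1.05) higher. Of the cholesterol synthesis genes, at percentiles 43.6 and 94.2 with 2 and 4 miRNAs, MSMO1 (1.63 and 1.99), INSIG1 (1.43 and 1.65) and HMGCS1 (1.39 and 1.37) were higher on those arrays, and TM7SF2 (−1.04 and −1.06) was lower. CYP3A5, a drug-metabolising enzyme, was higher by 1.93 in the day 7 control than in the day 5 control.

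Among genes measured on all 4 arrays by 1 probe set, those with large differences shared by all 3 arrays against the day 5 control, chosen after their values were seen, were MRAP2 (2.24, 2.29 and 2.60 in the 2-miRNA, 4-miRNA and day 7 arrays) and SLC25A24 (2.38, 2.40 and 1.95). On the lower side, WNT10B stood at −1.32, −1.67 and −1.22 and PGAM5 at −1.48, −1.21 and −1.45.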
